A study of Mus musculus with 20 samples.

How the data were processed

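The series holds 12 RNA libraries of sorted mouse skin cells, 7 ATAC libraries of epidermis and 1 p63 ChIP library of cultured keratinocytes. The ATAC and ChIP libraries have no processed files and were not analysed here. The RNA libraries were grouped as the labels name them, 3 per group: Het epidermis at E9 (replicates 1, 2 and 4), Het epidermis at E13, KO epidermis at E13 and Het dermis at E13. Per the labels' protocols, back skin was dissociated with collagenase and trypsin, GFP-positive epidermal cells and CD140a-positive dermal cells were sorted, and libraries were made with SMARTer and NEBNext directional kits. Per the labels, epidermal RNA was depleted of ribosomal RNA and dermal RNA selected with oligo(dT), so that tissue and library preparation coincide. The labels do not say that replicates are separate animals, and p-values measure only the spread between samples.

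Each deposited RNA file holds whole-number counts per gene symbol for 1 library, with the 5 summary lines that HTSeq appends. The submitters' processing notes name TopHat2, Bowtie2, HTSeq and the mm10 build, without versions or roles. The strand setting of the counting is not given in the sources used here. The files list 23432 symbols, of which 21570 matched a symbol in a RefSeq table of GRCm38.p6 and 1712 more a synonym. Coordinates come from that table. Of the 260 named genes with a position, 41 overlap another counted gene, and reads of such pairs, of antisense partners and of near-identical copies (histones, globins, structural RNAs) may be split or shared.

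Counts assigned to genes ranged from 3373819 to 7777808 per epidermal library and from 16931664 to 33386872 per dermal library. The summary lines took 48.8% to 63.8% of all entries in the epidermal files and 20.2% to 21.6% in the dermal files, mostly reads outside annotated genes (41.4% to 55.7% and 11.6% to 14.2%). The ribosomal precursor Rn45s took 2.90% to 9.69% of the epidermal and 11.2% to 30.7% of the dermal gene counts. Replicates differed by more than sampling noise, with chi-square per degree of freedom from 15.4 to 227 between pairs of replicates. A gene with no count in a group was set to 3 counts over the group to give a bound, and with 1 to 3 counts a ratio with its exact 95% counting interval is given. PCR copies are not independent molecules, and such bounds and intervals cover counting error only.

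Tests, gene lists, named genes and alternatives were fixed before the data were examined, except where the text says otherwise. The 3 epidermal comparisons came from 1 fit of the 9 epidermal libraries with 6 residual degrees of freedom, and epidermis against dermis from a fit of the 6 libraries compared. Both used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood F test), with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common biological coefficient of variation was 0.571 in the epidermal fit and 0.506 in the other. The smallest log2 change called was 0.48, 0.37, 0.42 and 0.43 in the 4 comparisons. CPM of single genes use TMM-scaled totals unless raw totals are named. The 28 gene lists cover epidermal layers and junctions, signalling pathways, other cell types the sort could hold, cell state, Hox genes and RNAs without poly(A) tails, and leave out Trp63 and Pdgfra. Lists with at least 5 tested genes, 26 per comparison, were tested with camera of limma 3.58.1 (log2 CPM with a prior count of 2, inter-gene correlation preset at 0.01), adjusted over the lists of a comparison. With the correlation estimated for each list, 2, 1, 1 and 0 lists passed. For the erythroid and macrophage lists too few genes passed the filter in the epidermal fit, and for the skeletal muscle and endoderm lists in the fit with dermis.

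Genes were named by a rule: Trp63; per comparison the 10 higher and 10 lower with the largest absolute log2 fold change among called genes with a mean of at least 10 CPM in 1 group, libraries that do not overlap and no predicted or clone name; and up to 4 members with the smallest adjusted p of each list described. Further genes are marked as chosen after their values were seen. Of the called genes that the rule names, 29 of 48, 54 of 76, 45 of 76 and 100 of 107 kept their call whichever library of the 2 compared groups was left out. Libraries of the third group in a fit were not left out for this count.

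The alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE size factors, no filter, a mean of at least 5 CPM, a 2-fold threshold, leaving out each replicate, all 12 libraries in 1 fit, leaving out RNAs without poly(A) tails, and a replicate block. For the lists they were an estimated correlation, fry, and a prior count of 0.5. Added after seeing the data were raw library totals, leaving out Rn45s and Lars2, fits of the 2 compared groups alone, and leaving out the library with fewest genes detected from each compared group.

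The procedure was tested on simulated data with the means, totals and spread of each comparison and 200 genes changed, 50 at each fold. A further list of 25 genes was raised 2-fold. At 1.5, 2, 4 and 8-fold, edgeR recovered 4%, 10%, 36% and 62% in KO against Het, 0%, 22%, 58% and 62% in E13 against E9, 2%, 14%, 34% and 56% in KO against E9, and 0%, 10%, 38% and 44% in epidermis against dermis. Unchanged genes made up 3.39% to 6.45% of those called. In these draws most changes of 2-fold or less were missed. Only 48 to 80 genes were called in them, against 287 to 4504 in the data, which makes their adjusted cutoff stricter. The recovery rates therefore do not carry over directly to the real comparisons.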

Results

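RNA was sequenced from sorted skin cells of mouse embryos that carried a GFP reporter in the delta-N promoter unit of Trp63, the gene of the transcription factor p63. The libraries form 4 groups of 3: heterozygous (Het) epidermis at embryonic day 9 (E9), Het epidermis at E13, knockout (KO) epidermis at E13 and Het dermis at E13. Epidermal cells were collected by GFP fluorescence and dermal cells by an antibody to CD140a, the product of Pdgfra. Genes with at least 1 count numbered from 10765 in E13 Het replicate 1 and 11275 in KO replicate 3 to 16200 in KO replicate 2. Levels are in CPM, mean ± SD of 3 libraries. Changes are folds, or log2 fold changes ± standard error. This error was taken back from the test, as the absolute log2 fold change over the square root of edgeR's F statistic. After a gene's change, p is edgeR's adjusted p. After a list's median log2 fold change, camera p is adjusted over the lists. Where leaving out 1 library of the compared groups ended a call, the highest p of the refits that lost it is given and, for genes with more than 3 counts in each group, "nearest" marks their log2 fold change nearest to 0.

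Trp63 itself was measured in every library. At E9 it stood at 303, 228 and 128 CPM, in E13 Het epidermis at 582, 636 and 477 CPM, and in KO epidermis at 24.9, 27.4 and 23.4 CPM. The 3 dermal libraries had 0.40, 0 and 1.80 CPM, from 8, 0 and 60 counts. The KO level, 25.2 ± 2.0 CPM, was 4.46% of the E13 Het level of 565 ± 80.8 CPM. Trp63 was 23.2-fold lower in KO than in E13 Het epidermis (log2 fold change -4.54 ± 0.28, adjusted p 1.5e-06). It rose from E9 to E13 in Het epidermis (1.36 ± 0.24, adjusted p 0.00305). The counts pool the isoforms of both promoters of the gene (GRCm38 chromosome 16, 25683763 to 25892088), so the delta-N isoform is not separated from the others.

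**Figure D1:**
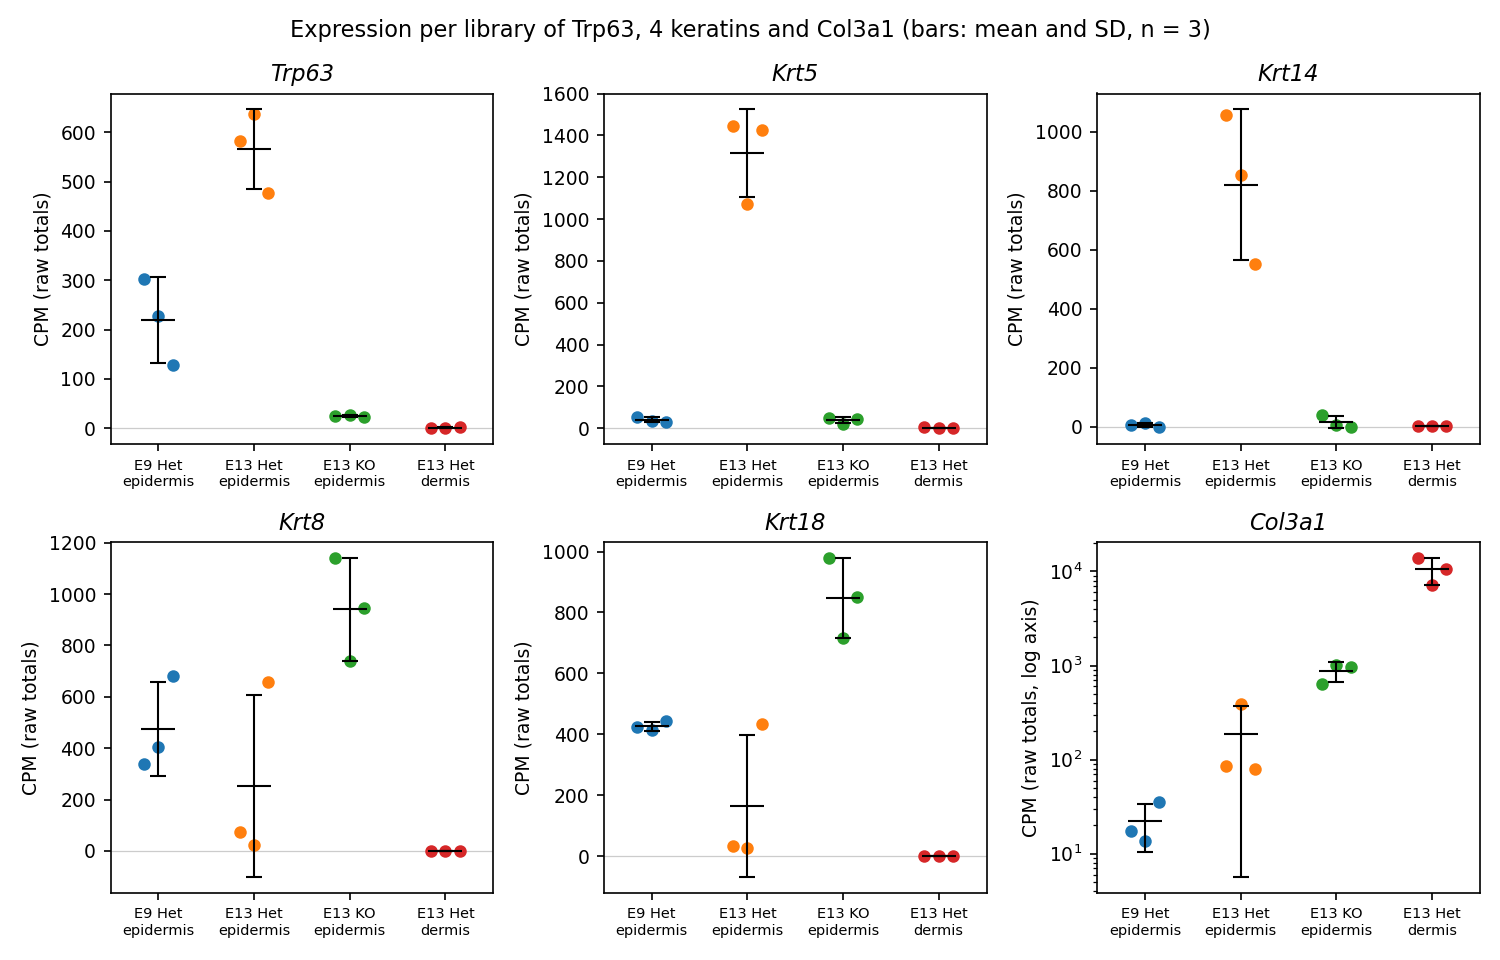
CPM from raw library totals (log axis for Col3a1 only) of Trp63, 4 keratin genes and Col3a1 in the 12 libraries, by group; points are libraries, and bars give the mean and SD of 3. Krt8 and Krt18 in E13 Het epidermis are high in replicate 3 alone, at 659 and 433 CPM.

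The first comparison, KO against Het epidermis at E13, asked which transcripts differ in skin epithelium of the KO. Many genes of the basal layer were lower in KO cells. Krt5, a basal keratin gene, fell from 1334 ± 201 to 37.2 ± 14.4 CPM (n = 3 each, 36-fold, p 9.4e-06). The hemidesmosome genes Col17a1 and Itgb4 fell from 297 ± 64.1 to 0.476 ± 0.824 and from 394 ± 94.5 to 72.4 ± 10.4 CPM. Dst, of the same structure, fell from 1183 ± 179 to 238 ± 66.3 CPM, and Notch1 fell 4.67-fold. In the other direction, Epcam, an adhesion molecule gene of simple epithelia, rose from 223 ± 21.9 to 509 ± 51.4 CPM (2.28-fold, p 0.00031).

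Of 13052 genes tested with edgeR, 287 passed an adjusted p of 0.05, 109 higher and 178 lower in KO. Of these, 229 differed at least 2-fold. The libraries of the groups did not overlap for 20.04% of the genes tested, where chance gives 10%. The number of called genes was 182 without KO replicate 1, 824 with DESeq2 and 656 with limma voom. Higher genes numbered 61 without KO replicate 1, 59 without KO replicate 3 and 178 without E13 Het replicate 3, where 170 were lower, so the excess of lower genes depended on that library.

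The genes with the largest rise in KO included Kcnt2, Cpa4, Sost, Hdac9, Glis3, Spsb4, Tcea3, Cux2 and Grin3a. Cpa4, a carboxypeptidase gene, reached 44.1 ± 10.5 CPM (6.58 ± 1.16, p 0.00655), and Glis3, a zinc finger factor gene, 46.9 ± 13.1 CPM (4.62 ± 0.79, p 0.00522). Grin3a, which encodes an NMDA receptor subunit, rose 10.5-fold (p 0.00130) and Cux2 11.4-fold (p 0.0185). The other log2 fold changes were 6.88 for Kcnt2, 5.79 for Sost, 4.93 for Hdac9, 4.19 for Spsb4 and 4.17 for Tcea3, with p from 0.0251 to 0.0421. Several of these calls were lost with 1 library left out, although the folds stayed large. Kcnt2 was not called without E13 Het 1 or 3 or E13 KO 1, 2 or 3 (p up to 0.0785, nearest 6.35). Sost was not called without E13 Het 1 or 2 or E13 KO 1 or 3 (p up to 0.190, nearest 5.09), and Hdac9 without E13 Het 3 or E13 KO 1 or 2 (p up to 0.168, nearest 4.36). Spsb4 was not called without E13 Het 2 or E13 KO 3 (p up to 0.136, nearest 3.21), and Tcea3 without E13 Het 3 or E13 KO 1, 2 or 3 (p up to 0.178, nearest 3.91). Cux2 was not called without E13 Het 2 or E13 KO 1 or 3 (p up to 0.105, nearest 3.38). Kcnt2, Glis3 and Grin3a overlap another annotated gene, and their counts are uncertain because the strand setting of the counting is not given in the sources used here.

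The 10 genes with the largest fall were Col17a1, Hpgds, Serpinb10, Mpped1, Edaradd, Rhov, Cdh13, Sv2b, Wnt3a and Fst. Hpgds, a prostaglandin D synthase gene, had 97.2 ± 26.2 CPM in Het and 3 counts in all KO libraries (571-fold, 95% counting interval 195 to 2773, p 4.7e-06). Serpinb10 had 52.4 ± 21 CPM in Het and 2 counts in KO (465-fold, 95% counting interval 128 to 3844, p 0.00025). Edaradd, the gene of the ectodysplasin receptor's adaptor, fell to 0.387 ± 0.536 CPM (-7.45 ± 0.76, p 6.8e-05). The log2 fold change was -7.60 ± 0.98 (p 0.00072) for Mpped1, -6.84 ± 1.01 (p 0.00232) for Cdh13, the T-cadherin gene, and -6.83 ± 0.99 (p 0.00267) for Sv2b, which overlaps another annotated gene. Wnt3a, a Wnt ligand gene, changed by -6.22 ± 1.30 (p 0.0276), and Fst, an activin antagonist gene, by -5.77 ± 1.0 (p 0.0204). Rhov had 3 counts in KO (143-fold, 95% counting interval 48.7 to 698, p 0.0384) and was not called without any 1 of the 6 libraries (p up to 0.221). Wnt3a was not called without E13 Het 2 or 3 or E13 KO 2 (p up to 0.165, nearest -5.84). Fst was not called without E13 Het 1 or 2 or E13 KO 1 (p up to 0.109, nearest -5.26).

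Among the gene lists, the basal keratin, hemidesmosome and basement membrane list fell as a group (median -1.60, camera p 1.3e-14, adjusted p = 0.0205 with an estimated correlation). Of 20 members, 0 were higher and 10 lower (1 and 15 adjusted over the list alone). Fermt1, the gene of the focal adhesion protein kindlin-1, changed by -2.63 ± 0.21 (p 7.5e-06). Krt14 stood at 16 ± 20.9 CPM in KO against 830.1 ± 241 CPM in Het, but its libraries varied widely and it did not pass (-5.64 ± 1.32, p 0.121, chosen after its values were seen). Genes widely described as p63-activated, several of which are also in the basal list, fell as well (median -2.01, camera p 7.8e-21, adjusted p = 0.0249 with an estimated correlation). Of 25 members, 0 were higher and 14 lower (0 and 19 adjusted over the list alone). The desmosome and adherens junction list was lower (median -0.41, camera p 0.00242, adjusted p = 0.368 with an estimated correlation), a call lost without KO replicate 2 (0.0505). Of 16 members, 1 was higher and 4 lower (1 and 6 adjusted over the list alone). The desmosomal plaque gene Dsp changed by -1.75 ± 0.15 (p 1.5e-05) and Pvrl1, the nectin-1 gene, by -2.46 ± 0.23 (p 3.0e-05). Pvrl2, the nectin-2 gene, was the higher member (1.13 ± 0.24, p 0.0213), lost without E13 Het 1 or E13 KO 3 (p up to 0.0945, nearest 0.85). Itgb4 and Dst overlap another annotated gene.

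The simple epithelium list of keratins, claudins and apical genes rose as a group (median 1.14, camera p 1.5e-05, adjusted p = 0.368 with an estimated correlation). Of 16 members, 1 was higher and 0 lower (7 and 0 adjusted over the list alone). The called member was Epcam. The next were Cldn6 (194 ± 31.3 CPM in KO against 90.9 ± 38 in Het, p 0.0588) and Cldn7 (116 ± 28.2 against 21.7 ± 23, p 0.109). Krt8 and Krt18, the keratin pair of simple epithelia, did not pass (p 0.665 and 0.519, chosen after their values were seen). E13 Het replicate 3 held 680 and 447 CPM of them, nearer to the KO means of 918 ± 208 and 827 ± 139 CPM than to the other Het libraries. The suprabasal and periderm list fell as a group (median -1.83, camera p 2.8e-05, adjusted p = 0.0706 with an estimated correlation). Of 10 members, 0 were higher and 1 lower (0 and 2 adjusted over the list alone). The called member was Sfn, the stratifin gene (-1.75 ± 0.36, p 0.0302), lost without E13 Het 1, 2 or 3 or E13 KO 2 (p up to 0.126, nearest -1.60). The epidermal transcription factor list did not move as a group (median 0.10, camera p 0.903), its median and mean being positive and camera's direction down. Of 25 members, 0 were higher and 2 lower (1 and 5 adjusted over the list alone). Among the lower ones was Grhl3 (-1.40 ± 0.32, p 0.0371), lost without E13 Het 1 or 3 or E13 KO 1, 2 or 3 (p up to 0.167, nearest -1.16).

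Signalling genes moved in part. The Notch list was lower in KO (median -0.91, camera p 0.00188, adjusted p = 0.0706 with an estimated correlation). Of 14 members, 1 was higher and 5 lower (1 and 7 adjusted over the list alone). Notch1 changed by -2.22 ± 0.23 (p 6.8e-05), the ligand genes Jag2 and Dll1 by -2.88 ± 0.37 (p 0.00135) and -2.76 ± 0.43 (p 0.00275), and the feedback gene Nrarp by -2.99 ± 0.50 (p 0.00457). The member that rose was Notch3, from 128 ± 50.01 to 348 ± 55.3 CPM (p 0.00858, chosen after its values were seen). The hair placode and follicle list was lower (median -0.87, camera p 0.00150, adjusted p = 0.333 with an estimated correlation). That call was lost without the 2 libraries with fewest genes detected, E13 Het replicate 1 and KO replicate 3, an alternative chosen after seeing the data (0.0519). Of 15 members, 2 were higher and 2 lower (2 and 6 adjusted over the list alone). Edaradd and Wnt10b (-3.18 ± 0.45, p 0.00149) fell, while Trps1 (1.42 ± 0.21, p 0.00151), which overlaps another annotated gene, and the BMP and Wnt antagonist gene Sostdc1 (0.86 ± 0.19, p 0.0257) rose. Sostdc1 was not called without E13 Het 1 or 2 or E13 KO 1 or 3 (p up to 0.143, nearest 0.75). The Wnt feedback list did not move as a group (median -0.08, camera p 0.516), its mean being slightly positive. Of 15 members, 0 were higher and 2 lower (1 and 4 adjusted over the list alone). These were Kremen2 (-2.51 ± 0.28, p 0.00016) and the receptor gene Fzd10 (-5.75 ± 0.52, p 0.00025). The BMP and TGF-beta list did not move either (median 0.29, camera p 0.621), its mean being negative. Of 16 members, 2 were higher and 1 lower (5 and 3 adjusted over the list alone). The higher members were Skil (0.86 ± 0.21, p 0.0476), lost without E13 Het 1 or 2 or E13 KO 1 or 3 (p up to 0.229, nearest 0.66), and Tgfb2 (1.26 ± 0.31, p 0.0488), lost without E13 Het 1 or 2 or E13 KO 1, 2 or 3 (p up to 0.180, nearest 1.01).

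Markers of other cell types were followed in the same fit. The neuron and neural tube list was higher in KO (median 2.17, camera p 0.00703, adjusted p = 0.437 with an estimated correlation). It was not called without E13 Het replicate 1 (0.0538), E13 Het replicate 3 (0.0707) or KO replicate 2 (0.250). Of 10 members, 1 was higher and 0 lower (1 and 0 adjusted over the list alone). Map2, a dendritic microtubule gene, rose from 10.8 ± 7.79 to 87.1 ± 40.7 CPM (2.99 ± 0.66, p 0.0408) but was not called without E13 Het 2 or E13 KO 1, 2 or 3 (p up to 0.150, nearest 2.59). The dermal mesenchyme list did not pass (median 0.45, camera p 0.376). Of 23 members, edgeR called 0 (2 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0. Col3a1, a fibrillar collagen gene, stood at 83.7, 406 and 81.8 CPM in the Het libraries and at 636, 983 and 933 CPM in the KO libraries (p 0.284). Col1a1 was high in replicate 2 of both groups, at 422 and 515 CPM of the raw totals against 42.95 to 150 in the other 4 libraries. The list of epithelial-mesenchymal transition factors did not pass (median 0.83, camera p 0.358). Of 14 members, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), the called one being Snai2 (-3.07 ± 0.59, p 0.0143). The endoderm list had camera p 0.227 (median 2.67), and 0.0187 without KO replicate 3. Of 5 members, edgeR called 0 (0 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0. Neither muscle (median 0.59, camera p 0.789, the mean being slightly negative), endothelium (median 0.19, camera p 0.753) nor melanocyte and neural crest genes (median 0.67, camera p 0.335) moved as lists. Of 8 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0 for muscle. Of 8 members, edgeR called 0 (0 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0 for endothelium. Of 6 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 1 for melanocytes.

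Lists of cell state moved little between KO and Het. The S phase and mitosis list was slightly lower (median -0.26, camera p 0.00246, adjusted p = 0.368 with an estimated correlation). Of 29 members, edgeR called 0 (6 at an unadjusted p under 0.05), DESeq2 1 and limma voom 1. The hypoxia and glycolysis list did not pass (median 0.30, camera p 0.1001). Of 15 members, 1 was higher and 0 lower (5 and 0 adjusted over the list alone), the called one being Bnip3 (1.99 ± 0.43, p 0.0254), lost without E13 Het 1 or 3 or E13 KO 2 or 3 (p up to 0.101, nearest 1.58). No call came from early embryonic genes (median -0.03, camera p 0.753, the mean being positive), p53 targets (median -0.61, camera p 0.177) or immediate early and heat shock genes (median -0.16, camera p 0.621). Of 14 members, edgeR called 0 (2 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0 for early embryonic genes. Of 16 members, edgeR called 0 (6 at an unadjusted p under 0.05), DESeq2 5 and limma voom 3 for p53 targets. Of 18 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0 for immediate early genes. Nor did Hox genes of groups 1 to 5 (median -0.18, camera p 0.819, the mean being positive) or 6 to 13 (median 0.75, camera p 0.541) pass. Of 15 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0 for groups 1 to 5. Of 18 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 1 for groups 6 to 13. Replication-dependent histones (median -0.07, camera p 0.516, the mean being positive) and structural RNAs without poly(A) tails (median -0.19, camera p 0.671) did not pass. Of 56 members, edgeR called 0 (2 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0 for histones. Of 43 members, edgeR called 0 (0 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0 for structural RNAs.

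**Figure D2:**
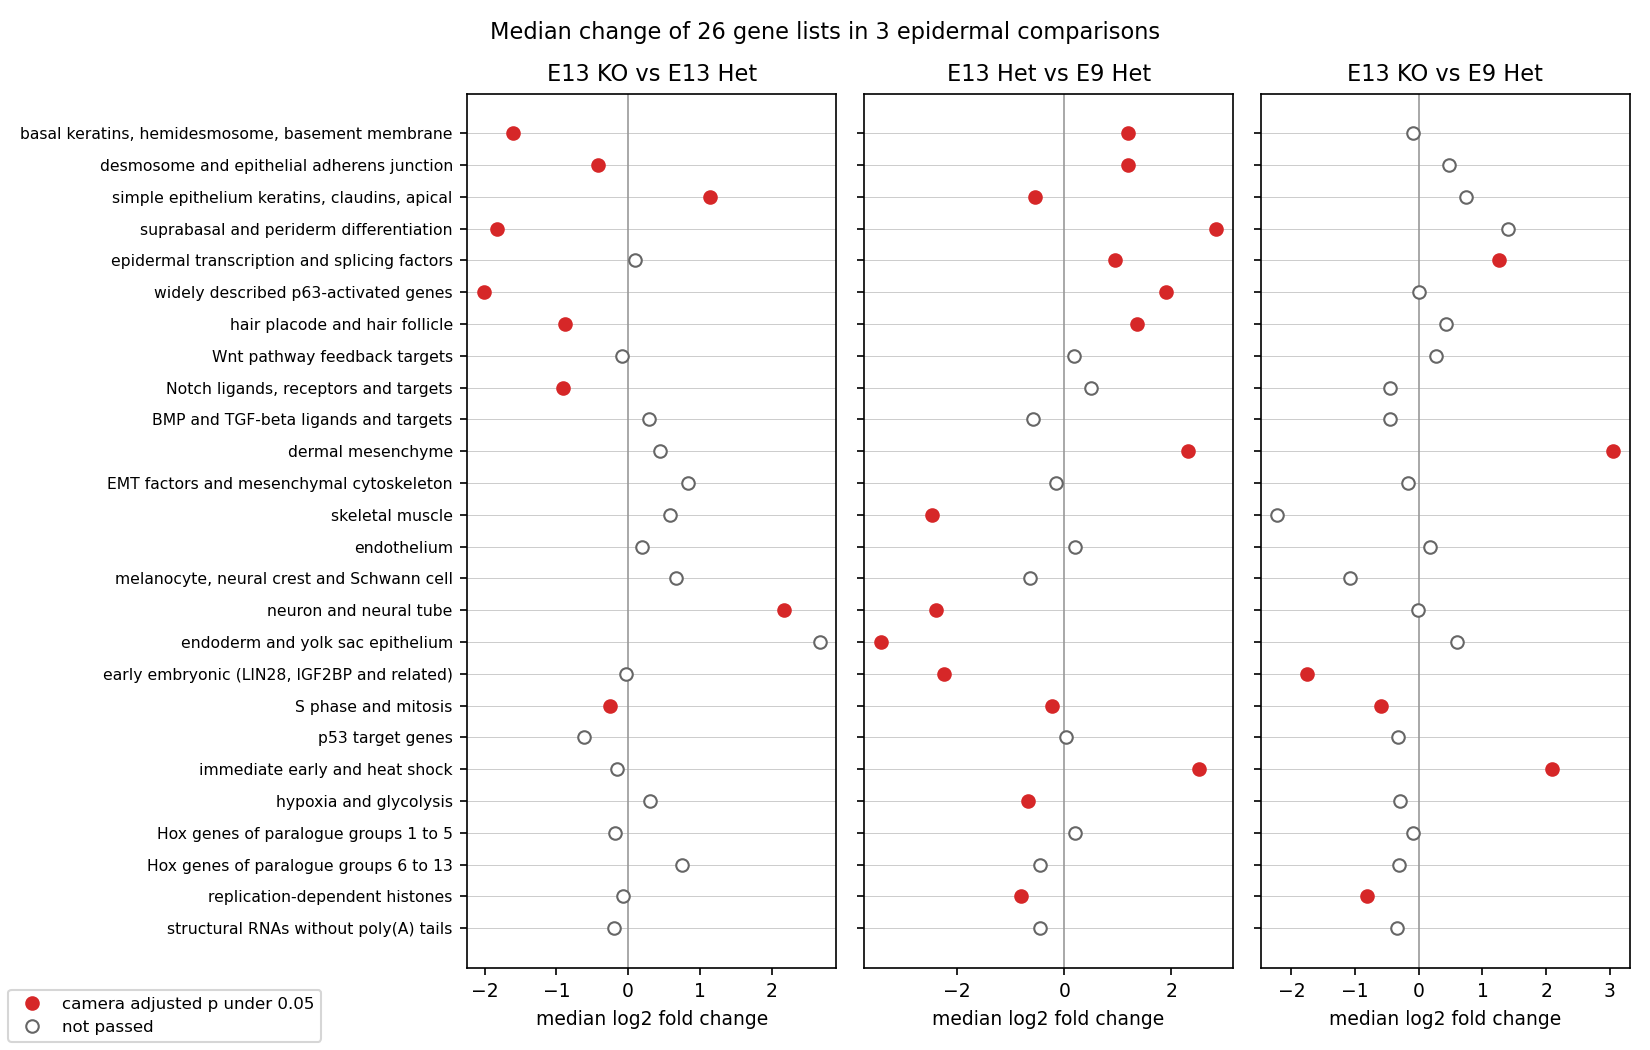
Median log2 fold change (horizontal axis) of the 26 gene lists tested in each of the 3 epidermal comparisons; filled points passed camera at an adjusted p under 0.05 and open points did not. The p63-activated list stands at -2.01 in KO against E13 Het and at 1.90 in E13 against E9 Het.

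The second comparison, E13 against E9 in Het epidermis, followed the early epidermis over development. Many basal and stratified-epithelium genes rose. Krt5 went from 40.8 ± 10.7 to 1334 ± 201 CPM (n = 3 each, 32.5-fold, p 5.8e-06) and Itgb4 from 13.4 ± 2.53 to 394 ± 94.5 CPM (29.5-fold, p 3.3e-08). Genes of the early embryo fell. Lin28a, the gene of a let-7-binding protein, went from 456 ± 70.3 to 0.422 ± 0.381 CPM (p 2.8e-06) and Sall4 from 182 ± 29.6 to 0.722 ± 0.626 CPM (p 0.00109). Of 13052 genes tested with edgeR, 952 passed an adjusted p of 0.05, 622 higher and 330 lower at E13, and 727 differed at least 2-fold. The groups did not overlap for 28.96% of genes, where chance gives 10%. The number called was 597 without E9 replicate 1, 569 without E9 replicate 2, 1997 with DESeq2 and 1729 with limma voom. Without these 2 libraries in turn, 404 and 406 genes were higher and 193 and 163 lower.

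The 10 genes with the largest rise had no count in any E9 library, so that only bounds can be given. Fst was higher by at least 387-fold (p 0.00201), the decorin gene Dcn by at least 357-fold (p 0.00010) and Serpinb10 by at least 294-fold (p 5.3e-05). The AMPA receptor subunit gene Gria2 was higher by at least 287-fold (p 1.7e-05), the desmosomal cadherin gene Dsg3 by at least 258-fold (p 0.00121), and Zfp750, the gene of a factor of terminal differentiation, by at least 242-fold (p 6.3e-05). Sv2b was higher by at least 241-fold (p 0.00032), Baalc by at least 161-fold (p 0.00278), Wnt3a by at least 148-fold (p 0.00288) and the cytochrome P450 gene Cyp2w1 by at least 144-fold (p 4.6e-05). Sv2b and Zfp750 overlap another annotated gene.

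Of the 10 genes with the largest fall, Lin28a changed by -9.87 ± 0.59 and Sall4 by -7.79 ± 0.97. Car4, a carbonic anhydrase gene, was lower at E13 by at least 241-fold (p 0.00046) and Ppp2r2c, a phosphatase subunit gene, by at least 169-fold (p 0.00388). Cdx2, a posterior homeobox gene, had 1 count in E13 Het epidermis (457-fold, 95% counting interval 81.6 to 18090, p 0.00520). Ptgis, a prostacyclin synthase gene, also had 1 (412-fold, 95% counting interval 73.5 to 16310, p 0.00989) and Chrdl1, a BMP antagonist gene, 2 (188-fold, 95% counting interval 51.5 to 1555, p 0.0115). The cardiac myosin gene Myh6 was lower by at least 88.2-fold (p 0.0324), Srms by at least 81.7-fold (p 0.0334) and the superoxide dismutase gene Sod3 by at least 66-fold (p 0.0298). Myh6, which overlaps another annotated gene, was not called without E9 Het 4 or E13 Het 2 or 3 (p up to 0.214). Srms was not called without E9 Het 1, 2 or 4 or E13 Het 2 or 3 (p up to 0.147), and Sod3 without E9 Het 1, 2 or 4 or E13 Het 2 or 3 (p up to 0.109). Cdx2 was not called without E9 Het 1 (p 0.0562), Ptgis without E9 Het 1 or 2 (p up to 0.0576), and Chrdl1 without E9 Het 4 (p 0.0503).

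Of the epidermal lists, the basal list rose (median 1.19, camera p 1.2e-05, adjusted p = 0.0681 with an estimated correlation). Of 20 members, 10 were higher and 2 lower (12 and 3 adjusted over the list alone). Besides Krt5 and Itgb4, Col7a1, the anchoring fibril collagen gene, changed by 4.36 ± 0.44 (p 3.1e-05) and Fras1 by 1.45 ± 0.13 (p 1.0e-05). The p63-activated list rose (median 1.90, camera p 4.3e-13, adjusted p = 0.0549 with an estimated correlation). Of 25 members, 15 were higher and 1 lower (20 and 2 adjusted over the list alone). The desmosome and adherens junction list rose (median 1.19, camera p 4.1e-05, adjusted p = 0.217 with an estimated correlation). Of 16 members, 7 were higher and 1 lower (11 and 1 adjusted over the list alone). Dsp went up by 1.88 ± 0.15 (p 5.3e-06) and the nectin gene Pvrl4 by 3.33 ± 0.34 (p 4.3e-05). The suprabasal and periderm list rose (median 2.84, camera p 1.9e-06, adjusted p = 0.0549 with an estimated correlation). Of 10 members, 5 were higher and 0 lower (7 and 0 adjusted over the list alone). The envoplakin gene Evpl rose from 38.6 ± 10.1 to 211 ± 144 CPM (p 0.00725) and the transglutaminase gene Tgm1 by 2.47 ± 0.54 (p 0.0111). Tgm1 was not called without E9 Het 1 or 4 or E13 Het 3 (p up to 0.0627, nearest 2.01). The transcription factor list rose (median 0.95, camera p 0.00354, adjusted p = 0.359 with an estimated correlation). Of 25 members, 6 were higher and 1 lower (11 and 3 adjusted over the list alone). Tfap2b (1.84 ± 0.16, p 6.5e-06) and the chromatin organiser gene Satb1 (2.50 ± 0.26, p 5.5e-05) were higher, and Msx2 lower (-2.85 ± 0.31, p 5.0e-05). Itgb4 and Col7a1 overlap another annotated gene.

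The simple epithelium list fell from E9 to E13 (median -0.54, camera p 0.00843, adjusted p = 0.423 with an estimated correlation), a call lost without E13 Het replicate 2 (0.165). Of 16 members, 0 were higher and 1 lower (0 and 2 adjusted over the list alone), the called one being Cldn6 (-1.39 ± 0.28, p 0.00659). Krt8 was at 484 ± 188 CPM at E9 and 259 ± 365 CPM at E13 (p 0.773), the latter from 74.7, 23.3 and 680 CPM. The hair placode and follicle list rose (median 1.35, camera p 0.00204, adjusted p = 0.217 with an estimated correlation). Of 15 members, 7 were higher and 0 lower (7 and 0 adjusted over the list alone). Wnt10b rose by 3.62 ± 0.46 (p 0.00025), Wnt10a by 3.69 ± 0.50 (p 0.00035) and the Wnt-responsive factor gene Lef1 by 1.41 ± 0.23 (p 0.00163). The Notch list did not pass (median 0.50, camera p 0.0748). Of 14 members, 5 were higher and 0 lower (6 and 1 adjusted over the list alone). Notch1 rose 8.63-fold, p 2.7e-06, and the ligand gene Dll1 by 2.21 ± 0.42 (p 0.00461). The Wnt feedback list did not move (median 0.19, camera p 0.936, the mean being negative). Of 15 members, 4 were higher and 2 lower (4 and 4 adjusted over the list alone), Kremen2 (2.74 ± 0.28, p 3.2e-05) and Fzd10 (3.87 ± 0.47, p 0.00058) being higher. The BMP and TGF-beta list did not pass (median -0.58, camera p 0.0674, 0.0427 without E13 Het replicate 3). Of 16 members, 2 were higher and 2 lower (3 and 5 adjusted over the list alone). Msx1 changed by -4.60 ± 0.44 (p 1.8e-05) and Bmp4, which overlaps another gene, by -2.76 ± 0.46 (p 0.00157). Fst and Bmp7 (1.34 ± 0.28, p 0.00884) rose, Bmp7 not being called without E9 Het 4 (p 0.0551, nearest 1.25).

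Mesenchymal matrix genes were also higher at E13. The dermal mesenchyme list rose (median 2.32, camera p 5.1e-05, adjusted p = 0.250 with an estimated correlation). Of 23 members, 5 were higher and 0 lower (9 and 0 adjusted over the list alone). Postn, the periostin gene, went from 17.7 ± 2.73 to 507 ± 46.8 CPM (28.5-fold, p 1.1e-09). The collagen genes Col5a1 and Col5a2 changed by 1.56 ± 0.17 (p 5.0e-05) and 2.32 ± 0.38 (p 0.00404), and Dcn was among the 10 largest rises. E13 Het replicate 2 held the highest level of 83.3% of the members that did not pass, 15 of 18, and of the called members other than Postn. Its Col1a1 level was 422 CPM of the raw total against 60.5 and 42.95 in replicates 1 and 3. The list of transition factors and mesenchymal cytoskeleton did not move as a group (median -0.16, camera p 0.801). Of 14 members, 2 were higher and 1 lower (3 and 2 adjusted over the list alone). Sparc rose by 1.77 ± 0.19 (p 4.6e-05) and Vim by 1.44 ± 0.25 (p 0.00209). The fibronectin gene Fn1 changed by -2.26 ± 0.37 (p 0.00640) and was not called without E13 Het 3 (p 0.0535, nearest -2.27).

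The early embryonic, neuron, muscle and endoderm lists were lower at E13. The early embryonic list fell (median -2.24, camera p 8.1e-09, adjusted p = 0.0308 with an estimated correlation). Of 14 members, 0 were higher and 7 lower (0 and 9 adjusted over the list alone). Igf2bp1 (-1.12 ± 0.13, p 0.00011), which overlaps another gene, and the DNA methyltransferase gene Dnmt3b (-1.74 ± 0.22, p 0.00022) were among them. The neuron list was lower (median -2.39, camera p 0.00130, adjusted p = 0.250 with an estimated correlation). Of 10 members, edgeR called 0 (3 at an unadjusted p under 0.05), DESeq2 3 and limma voom 2. The skeletal muscle list was lower (median -2.48, camera p 0.0117, adjusted p = 0.271 with an estimated correlation). Of 8 members, edgeR called 0 (2 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0. E9 replicate 4 held 49.97 CPM of the sarcomeric actin gene Actc1 and 185 CPM of the titin gene Ttn. E9 replicates 1 and 2 held at most 3.45 and 35.8 CPM of them, and without replicate 4 the list was not called (0.0647, and 0.246 with E13 Het replicate 1 left out too). The endoderm list was lower (median -3.43, camera p 0.0130, adjusted p = 0.260 with an estimated correlation), a call lost without E13 Het replicate 3 (0.0601). Of 5 members, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), the called one being Cdx2. The melanocyte and neural crest list did not pass (median -0.64, camera p 0.141). Of 6 members, 0 were higher and 1 lower (0 and 2 adjusted over the list alone), the called one being Kit (-4.21 ± 1.18, p 0.0481), lost without any 1 of the 6 libraries (p up to 0.170, nearest -3.68). Endothelium did not pass (median 0.20, camera p 0.417, camera's direction being down). Of 8 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 1. Hox genes of groups 1 to 5 (median 0.20, camera p 0.926, the mean being negative) and 6 to 13 (median -0.46, camera p 0.926, 0.00783 without E9 replicate 4) did not pass. Of 15 members, edgeR called 0 (2 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0 for groups 1 to 5. Of 18 members, edgeR called 0 (4 at an unadjusted p under 0.05), DESeq2 3 and limma voom 2 for groups 6 to 13.

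Stress, glycolysis and proliferation genes also differed with stage. The immediate early and heat shock list was higher at E13 (median 2.52, camera p 8.5e-05, adjusted p = 0.217 with an estimated correlation). This list was chosen to follow the response of cells to dissociation, and handling of the tissue was not tested apart from stage. Of 18 members, 6 were higher and 1 lower (10 and 1 adjusted over the list alone). Atf3 rose by 3.76 ± 0.79 (p 0.00869), and the chaperone gene Hsp90aa1 was the lower member (-0.86 ± 0.14, p 0.00128). The hypoxia and glycolysis list fell (median -0.67, camera p 0.00980, adjusted p = 0.217 with an estimated correlation). Of 15 members, 1 was higher and 6 lower (1 and 7 adjusted over the list alone), among the lower ones Ldha (-1.41 ± 0.17, p 0.00012), Pgk1 (-1.28 ± 0.21, p 0.00122) and Bnip3 (-2.34 ± 0.43, p 0.00376). The S phase and mitosis list was slightly lower (median -0.23, camera p 0.00980, adjusted p = 0.271 with an estimated correlation), a call lost without E13 Het replicate 3 (0.109). Of 29 members, 0 were higher and 2 lower (0 and 4 adjusted over the list alone). Ccnb1 (-0.84 ± 0.23, p 0.0381) was not called without E9 Het 1, 2 or 4 or E13 Het 1 or 3 (p up to 0.119, nearest -0.72), and Bub1 (-0.98 ± 0.28, p 0.0498) without E9 Het 1, 2 or 4 or E13 Het 1 or 3 (p up to 0.178, nearest -0.78). The replication-dependent histone list was lower (median -0.80, camera p 2.4e-06, adjusted p = 0.217 with an estimated correlation). Of 56 members, 0 were higher and 3 lower (0 and 8 adjusted over the list alone), Hist1h1e (-0.72 ± 0.17, p 0.0176) not being called without E9 Het 2 (p 0.108, nearest -0.60). Counts of such close copies may be shared between them. The p53 targets did not pass (median 0.02, camera p 0.525). Of 16 members, 1 was higher and 0 lower (1 and 0 adjusted over the list alone), the called one being Plk2 (1.34 ± 0.19, p 0.00042). Structural RNAs did not pass (median -0.46, camera p 0.221). Of 43 members, edgeR called 0 (3 at an unadjusted p under 0.05), DESeq2 2 and limma voom 0.

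The changes of the KO and of the stage were then set against each other gene by gene. Of 158 genes called in both, 137 moved in opposite directions. Of these, 107 were lower in KO and higher at E13, as Krt5, Col17a1, Itgb4, Dsp and Notch1, and 30 were higher in KO and lower at E13. The 107 became 70 without E13 Het replicate 1, and the 30 became 17 without E9 replicate 2 and 62 without E13 Het replicate 3. Independent lists of these sizes would share 8.48 and 2.76 genes in these directions. Genes higher in both numbered 17 and lower in both 4, where independence gives 5.19 and 4.50. Across the 13052 genes, which are not independent replicates, the log2 fold changes correlated at r = -0.368. Both comparisons use the same E13 Het libraries, so unchanged groups were simulated 60 times with them. These gave r = -0.498 ± 0.0130 (SD), stronger than the observed r, and at most 1 gene called in opposite directions. Groups without real changes offer almost no gene to be called in both comparisons, so that count decides nothing. The covariance was -0.672 against a simulated -0.520 ± 0.0226, a difference of -0.152. The covariance depended on single libraries, at -2.122 without E13 Het replicate 2 and -1.108 without E13 Het replicate 3, for which the simulation was not repeated. The 3 control libraries are too few to be split, and part of the excess may come from the shared controls. Leaving out 1 library gave r from -0.254 without KO replicate 2 to -0.594 without E13 Het replicate 2.

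**Figure D3:**
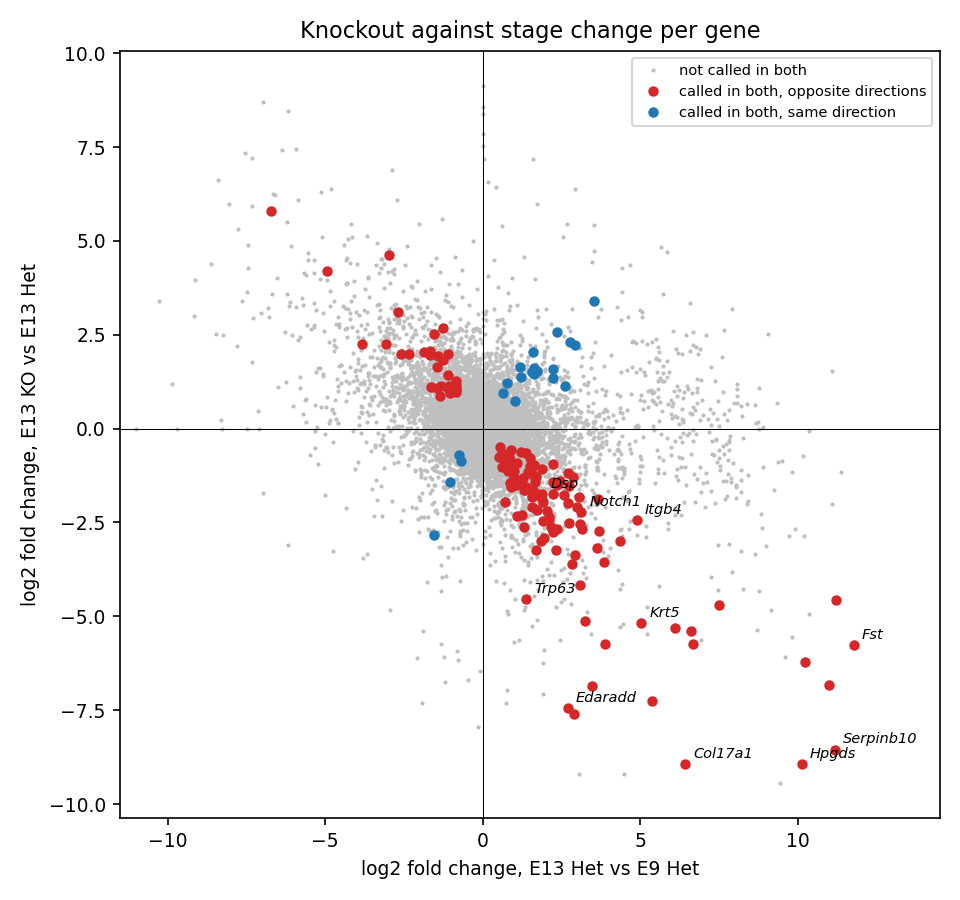
Log2 fold change of KO against Het epidermis at E13 (vertical axis) against that of E13 against E9 Het epidermis (horizontal axis) for 13052 genes, from the fit of 9 libraries in groups of 3. Of the genes called in both comparisons, 137 changed in opposite directions and 21 in the same direction.

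The third comparison set KO epidermis at E13 against Het epidermis at E9 and asked where the KO cells stand relative to the earlier stage. Part of the basal set lay below the E9 level and part above it. Fermt1 was 5.35-fold lower in KO than at E9 (28.9 ± 3.08 against 155 ± 27.6 CPM, n = 3 each, p 7.7e-06) and Itga3, the integrin alpha 3 gene, 2.90-fold lower (p 0.00010). Itgb4 was 5.42-fold higher (p 1.8e-05) and Fras1 2.45-fold higher (p 2.8e-05). Lin28a was low in KO as well, at 0.930 ± 1.10 CPM against 456 ± 70.3 (-8.67 ± 0.54, p 3.8e-06). Trp63 was 9.04-fold lower in KO than at E9 (24.6 ± 2.04 against 223 ± 85.7 CPM, p 8.2e-06). Of 13052 genes tested with edgeR, 1001 passed an adjusted p of 0.05, 603 higher and 398 lower in KO, 732 of them at least 2-fold. The groups did not overlap for 31.9% of genes, where chance gives 10%. The number called was 606 without E9 replicate 1, 557 without E9 replicate 2, 592 without KO replicate 1, 2172 with DESeq2 and 2575 with limma voom. Without these 3 libraries in turn, 403, 383 and 385 genes were higher and 203, 174 and 207 lower. Itgb4 overlaps another annotated gene.

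The largest rises were again against no count at E9. Gria2 was higher by at least 817-fold (p 5.0e-06), the enamel protein gene Amtn by at least 252-fold (p 0.00158), Fstl5 by at least 180.3-fold (p 0.00444), Serpinb7 by at least 152-fold (p 0.00560) and Cyp2w1 by at least 149-fold (p 4.9e-05). Fam135b was higher by at least 148-fold (p 0.00407), Dcn by at least 146-fold (p 0.00026), Nkain2 by at least 115-fold (p 0.00124) and the interferon-induced gene Oasl2 by at least 105-fold (p 0.0126). Oasl2 was not called without E13 KO 1 (p 0.0617). Hic1, a transcriptional repressor gene that overlaps Smg6, had 3 counts at E9 and 221 ± 36.7 CPM in KO (1122-fold, 95% counting interval 384 to 5445, p 8.7e-09). Of the largest falls, Car4 was lower by at least 237-fold (p 0.00051), Myh6 by at least 86.5-fold (p 0.0317) and the posterior homeobox gene Cdx1 by at least 77-fold (p 0.0185). Cdx2 (449-fold, 95% counting interval 80.1 to 17760, p 0.00622), Scn4b (324-fold, 95% counting interval 57.7 to 12840, p 0.00995) and Zscan10 (238-fold, 95% counting interval 42.2 to 9421, p 0.0407) each had 1 count in KO. The forkhead gene Foxi2 changed by -7.03 ± 1.53 (p 0.0187), Ppp2r2c by -6.88 ± 1.43 (p 0.0110) and Prtg by -6.79 ± 1.27 (p 0.0249). Myh6 was not called without E9 Het 4 or E13 KO 1, 2 or 3 (p up to 0.198), and Cdx1 without E9 Het 1, 2 or 4 or E13 KO 1 or 2 (p up to 0.0741). Cdx2 was not called without E9 Het 1 or 2 (p up to 0.0647). Scn4b was not called without E9 Het 1 or E13 KO 1 (p up to 0.0928), and Zscan10 without E9 Het 1, 2 or 4 or E13 KO 1 or 2 (p up to 0.148). Foxi2 was not called without E13 KO 1, 2 or 3 (p up to 0.115, nearest -6.64). Ppp2r2c was not called without E9 Het 1 or 2 (p up to 0.104, nearest -6.58), and Prtg without any 1 of the 6 libraries (p up to 0.105, nearest -6.37).

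Lists that passed in this comparison did so in both directions. The early embryonic list was lower in KO than at E9 (median -1.76, camera p 1.6e-09, adjusted p = 0.0230 with an estimated correlation). Of 14 members, 0 were higher and 8 lower (0 and 12 adjusted over the list alone). Igf2bp1 (-1.34 ± 0.13, p 2.5e-05) and Dnmt3b (-1.66 ± 0.22, p 0.00034) were among them. The S phase and mitosis list was lower (median -0.60, camera p 2.1e-06, adjusted p = 0.390 with an estimated correlation). Of 29 members, 0 were higher and 8 lower (0 and 14 adjusted over the list alone), as the checkpoint kinase gene Bub1b (-0.81 ± 0.17, p 0.00753). The histone list was lower (median -0.82, camera p 2.1e-07, adjusted p = 0.430 with an estimated correlation). Of 56 members, 0 were higher and 8 lower (0 and 10 adjusted over the list alone), as Hist1h1e (-1.02 ± 0.17, p 0.00172). The epidermal transcription factor list was higher (median 1.27, camera p 0.00896, adjusted p = 0.618 with an estimated correlation). Of 25 members, 9 were higher and 1 lower (14 and 3 adjusted over the list alone). Tfap2b rose by 1.93 ± 0.16 (p 4.2e-06) and Satb1 by 2.31 ± 0.26 (p 0.00011), and Msx2 was lower (-2.82 ± 0.31, p 5.3e-05). The dermal mesenchyme list was higher (median 3.05, camera p 7.7e-07, adjusted p = 0.461 with an estimated correlation). Of 23 members, 5 were higher and 0 lower (11 and 0 adjusted over the list alone), as Postn (4.88 ± 0.17, p 9.9e-10) and Col5a1 (1.49 ± 0.17, p 8.1e-05). Raw Col1a1 was 515 CPM in KO replicate 2 against 150 and 99 CPM in KO replicates 1 and 3. Dcn, among the largest rises here, stood at 0.954%, 3.35% and 1.73% of its dermal level in KO replicates 1, 2 and 3. Col3a1 stood at 4.56%, 7.12% and 6.52% of its own, so dermal RNA carried through the sort may account for the rise of Dcn. The immediate early list, chosen to follow the response to dissociation, was higher (median 2.09, camera p 0.00103, adjusted p = 0.618 with an estimated correlation). Handling was not tested apart from the groups here either. Of 18 members, 4 were higher and 1 lower (9 and 2 adjusted over the list alone), as Atf3 (3.83 ± 0.79, p 0.00808).

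The remaining lists did not pass as groups. The basal list had 3 higher and 6 lower of 20 (6 and 6 adjusted over the list alone), camera p 0.513. The p63-activated list had 8 higher and 6 lower of 25 (9 and 9 adjusted over the list alone), camera p 0.994. The desmosome list had 4 higher and 0 lower of 16 (6 and 2 adjusted over the list alone), camera p 0.230, with Pvrl4 at 3.22 ± 0.34 (p 5.3e-05). The simple epithelium list had 2 higher and 0 lower of 16 (3 and 0 adjusted over the list alone), camera p 0.293, with Epcam at 0.94 ± 0.14 (p 0.00085). The suprabasal list had 2 higher and 0 lower of 10 (4 and 0 adjusted over the list alone), camera p 0.230. The hair list had 2 higher and 1 lower of 15 (6 and 3 adjusted over the list alone), camera p 0.718, with Wnt10a at 4.07 ± 0.51 (p 0.00019) and Edaradd at -4.76 ± 0.72 (p 0.00092). The Notch list had 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone), camera p 0.375, with Jag2 at -1.97 ± 0.36 (p 0.00541). The Wnt list had 1 higher and 3 lower of 15 (2 and 3 adjusted over the list alone), camera p 0.744, with Tcf7 at -3.35 ± 0.44 (p 0.00025). The BMP list had 2 higher and 3 lower of 16 (3 and 5 adjusted over the list alone), camera p 0.285, with Msx1 at -3.45 ± 0.41 (p 0.00013). Transition factors had 2 higher and 0 lower of 14 (3 and 1 adjusted over the list alone), camera p 0.752. Melanocyte genes had 1 higher and 0 lower of 6 (1 and 0 adjusted over the list alone), camera p 0.650, and endoderm genes 0 higher and 1 lower of 5 (0 and 1 adjusted over the list alone), camera p 0.345. The p53 targets had 1 higher and 0 lower of 16 (1 and 0 adjusted over the list alone), camera p 0.513, with Plk2 at 1.93 ± 0.19 (p 2.2e-05). Hypoxia genes had 1 higher and 2 lower of 15 (1 and 3 adjusted over the list alone), camera p 0.230, with Ldha at -0.83 ± 0.17 (p 0.00718).

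Further lists gave no called gene between KO and E9. Of 8 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 2 for muscle (camera p 0.0761, 0.0497 without E9 replicate 1). Of 8 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 1 for endothelium (camera p 0.718). Of 10 members, edgeR called 0 (3 at an unadjusted p under 0.05), DESeq2 2 and limma voom 2 for neurons (camera p 0.608). Of 15 members, edgeR called 0 (0 at an unadjusted p under 0.05), DESeq2 1 and limma voom 1 for Hox groups 1 to 5 (camera p 0.994). Of 18 members, edgeR called 0 (1 at an unadjusted p under 0.05), DESeq2 1 and limma voom 2 for groups 6 to 13 (camera p 0.718). Of 43 members, edgeR called 0 (4 at an unadjusted p under 0.05), DESeq2 3 and limma voom 2 for structural RNAs (camera p 0.230). The median and camera's direction differed in sign for the Wnt, transition factor, endothelium, endoderm and both Hox lists.

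The fourth comparison, Het epidermis against Het dermis at E13, separated the sorted layers of the skin. Some epithelial genes were almost absent from the dermal libraries, and others were lower there. The giant protocadherin gene Fat2 had 221 ± 68.6 CPM in epidermis and no count in dermis (n = 3 each, at least 4370-fold, p 3.5e-05). Krt14 had 697 ± 189 CPM against 2.54 ± 1.09 (282-fold, p 2.1e-05). Matrix genes lay on the other side, as Col6a2 with 17 ± 10.8 CPM in epidermis and 1943 ± 333 in dermis (-6.82 ± 0.54, p 0.00016, chosen after its values were seen). Vim had 210.1 ± 48.6 and 1662 ± 96.2 CPM (-2.98 ± 0.21, p 5.1e-05). Epidermal RNA had been depleted of ribosomal RNA and dermal RNA selected on poly(A), so tissue and library preparation cannot be told apart for any gene here. Of 12975 genes tested with edgeR, 4504 passed an adjusted p of 0.05, 2140 higher and 2364 lower in epidermis, and 3585 differed at least 2-fold. The share of called genes that were higher was 47.5%, and 68.7% when raw library totals replaced TMM scaling, which moved the median of all genes by 0.44 on the log2 scale. The groups did not overlap for 56.1% of genes, where chance gives 10%, and 2934 genes were called without dermis replicate 3. Without dermis replicates 1, 2 and 3 in turn, 1509, 1331 and 1479 genes were lower and 1820, 1691 and 1455 higher, so which side held more genes depended on the libraries.

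Of the 10 genes highest in epidermis relative to dermis, 7 had no dermal count. Besides Fat2, these were Fam83b (at least 2097-fold, p 2.6e-05), the claudin gene Cldn6 (at least 1459-fold, p 0.00012) and the potassium channel gene Kcnh7 (at least 1355-fold, p 7.2e-05). Rassf9 (at least 1104-fold, p 0.00020), the non-muscle myosin gene Myh14 (at least 1038-fold, p 0.00093) and Dsg3 (at least 845-fold, p 0.00023) were the others. Fermt1 had 1 dermal count (9262-fold, 95% counting interval 1661 to 365900), the desmoglein gene Dsg2 had 2 (8451-fold, 95% counting interval 2338 to 69800), and the GABA receptor subunit gene Gabrp had 0.103 ± 0.179 CPM in dermis (12.39 ± 1.41, p 0.00081). Of the 10 lowest, the chemerin receptor gene Cmklr1 was lower by at least 120.2-fold (p 0.00122), Enho by at least 108-fold (p 0.00135), the immune receptor gene Cd40 by at least 91.4-fold (p 0.00273) and Rpl39l by at least 89.6-fold (p 0.00262). The lysozyme gene Lyz2 was lower by at least 88.9-fold (p 0.00316), Tmem132b by at least 86.2-fold (p 0.00286) and Tm4sf1 by at least 64.3-fold (p 0.00619). Epha8 had 1 count in epidermis (1666-fold, 95% counting interval 299 to 65830, p 2.1e-05). The embryonic globin gene Hbb-y stood at 792 ± 555 CPM in dermis (-9.74 ± 1.07, p 0.00074). The adult globin transcript Beta-s was at 46.5 ± 35 CPM, with 1 epidermal count (1048-fold, 95% counting interval 188 to 41390, p 0.00069). Globin genes are close copies of each other, and Kcnh7 and Enho overlap another annotated gene.

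Epithelial lists were higher in epidermis. The basal list was higher (median 7.46, camera p 8.4e-10, adjusted p = 0.0993 with an estimated correlation). Of 20 members, 18 were higher and 2 lower (18 and 2 adjusted over the list alone). The p63-activated list was higher (median 7.16, camera p 5.9e-17, adjusted p = 0.0798 with an estimated correlation). Of 25 members, 24 were higher and 0 lower (24 and 0 adjusted over the list alone), as the Notch ligand gene Jag2 (6.77 ± 0.22, p 8.4e-06). The desmosome list was higher (median 8.69, or 8.0 with members at their bounds, camera p 9.9e-11, adjusted p = 0.0993 with an estimated correlation). Of 16 members, 14 were higher and 0 lower (14 and 0 adjusted over the list alone), as the E-cadherin gene Cdh1 (11.83 ± 0.69, p 5.3e-05). The simple epithelium list was higher (median 8.11, or 7.51 with members at their bounds, camera p 2.4e-09, adjusted p = 0.179 with an estimated correlation). Of 13 members, 12 were higher and 0 lower (12 and 0 adjusted over the list alone), as the ezrin gene Ezr (4.02 ± 0.31, p 7.2e-05). The suprabasal list was higher (median 5.85, camera p 1.5e-05, adjusted p = 0.0993 with an estimated correlation). Of 10 members, 7 were higher and 0 lower (7 and 0 adjusted over the list alone), as Krt17 (9.06 ± 0.87, p 0.00037). The transcription factor list was higher (median 5.92, camera p 1.3e-10, adjusted p = 0.0798 with an estimated correlation). Of 23 members, 17 were higher and 1 lower (18 and 2 adjusted over the list alone), as Satb1 (5.92 ± 0.34, p 2.6e-05). Hair genes were higher (median 3.06, camera p 3.1e-07, adjusted p = 0.0993 with an estimated correlation). Of 14 members, 11 were higher and 1 lower (12 and 1 adjusted over the list alone), as Lgr6 (4.85 ± 0.36, p 6.1e-05). Early embryonic genes were higher (median 1.61, camera p 0.0305, adjusted p = 0.316 with an estimated correlation), a call lost without dermis replicate 3 (0.0566). Of 10 members, 4 were higher and 0 lower (4 and 0 adjusted over the list alone), as Igf2bp1 (1.72 ± 0.15, p 0.00013). Of the transcripts without poly(A) tails, which the dermal library preparation selects against, most histones but only some structural RNAs were called higher in epidermis. Histones had 39 higher and 0 lower of 49 (42 and 0 adjusted over the list alone), as Hist2h2bb (9.31 ± 0.47, p 2.4e-05), and passed as a list (median 4.50, camera p 1.5e-18, adjusted p = 0.117 with an estimated correlation). Structural RNAs had 9 higher and 1 lower of 38 (9 and 1 adjusted over the list alone), as Rpph1 (6.86 ± 0.54, p 0.00016), and passed (median 1.15, camera p 0.00588, adjusted p = 0.389 with an estimated correlation), while the ribosomal precursor Rn45s was lower (-2.66 ± 0.45, p 0.00311).

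Mesenchymal, blood and stress lists were higher in dermis. The dermal mesenchyme list was lower in epidermis (median -5.26, camera p 9.9e-11, adjusted p = 0.242 with an estimated correlation). Of 25 members, 0 were higher and 24 lower (0 and 24 adjusted over the list alone), as Thy1 (-7.97 ± 0.58, p 8.5e-05) and Fstl1 (-2.41 ± 0.21, p 0.00013). The transition factor and mesenchymal cytoskeleton list was lower (median -3.09, camera p 6.1e-05, adjusted p = 0.242 with an estimated correlation). Of 14 members, 0 were higher and 12 lower (0 and 13 adjusted over the list alone), as Sparc (-1.72 ± 0.18, p 0.00032). The erythroid list was lower (median -8.79, or -6.85 with members at their bounds, camera p 0.00350, adjusted p = 0.373 with an estimated correlation). Of 6 members, 0 were higher and 4 lower (0 and 4 adjusted over the list alone), as the globin gene Hba-x (-7.97 ± 0.96, p 0.00105). Without dermis replicate 3 too few erythroid genes passed the filter for a test. The macrophage and leukocyte list was lower (median -5.20, camera p 0.00057, adjusted p = 0.373 with an estimated correlation). Of 13 members, 1 was higher and 9 lower (1 and 9 adjusted over the list alone), as the mannose receptor gene Mrc1 (-5.93 ± 1.08, p 0.00432). The immediate early list was lower (median -2.11, camera p 0.00062, adjusted p = 0.373 with an estimated correlation). Of 18 members, 0 were higher and 12 lower (1 and 15 adjusted over the list alone), as Ier2 (-2.59 ± 0.28, p 0.00033). Pdgfra, whose product marked the dermal sort, stood at 443 to 887 CPM of the raw totals in dermis and at 11.5 to 97.9 in the 9 epidermal libraries.

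Members of the other lists moved both ways between the layers. The Wnt list had 5 higher and 8 lower of 16 (5 and 9 adjusted over the list alone), camera p 0.480, with Fzd10 at 3.58 ± 0.21 (p 3.2e-05) and the Wnt inhibitor gene Apcdd1 at -4.10 ± 0.30 (p 5.7e-05). The Notch list had 5 higher and 2 lower of 14 (5 and 2 adjusted over the list alone), camera p 0.164. The BMP list had 4 higher and 4 lower of 17 (5 and 6 adjusted over the list alone), camera p 0.950, with Id1 at -3.10 ± 0.22 (p 5.0e-05) and Bmp7 at 3.15 ± 0.29 (p 0.00016). S phase genes had 4 higher and 5 lower of 29 (4 and 4 adjusted over the list alone), camera p 0.349, with the proliferation marker gene Mki67 at 1.95 ± 0.18 (p 0.00017). The p53 targets had 5 higher and 5 lower of 17 (5 and 5 adjusted over the list alone), camera p 0.950, and hypoxia genes 3 higher and 7 lower of 15 (3 and 7 adjusted over the list alone), camera p 0.377. Endothelium had 0 higher and 1 lower of 9 (0 and 0 adjusted over the list alone), camera p 0.354 and 0.0425 without E13 Het replicate 2. Neurons had 0 higher and 1 lower of 5 (0 and 1 adjusted over the list alone), camera p 0.192 and 0.0495 without E13 Het replicate 2. The melanocyte and neural crest list had 1 higher and 1 lower of 8 (1 and 1 adjusted over the list alone), camera p 0.930, with the receptor gene Ngfr at -5.78 ± 0.83 (p 0.00215) and Erbb3 at 6.57 ± 1.19 (p 0.00570). Hox genes of groups 1 to 5 had 3 higher and 1 lower of 13 (3 and 1 adjusted over the list alone), camera p 0.207 and 0.0450 without dermis replicate 3. Hox genes of groups 6 to 13 had 4 higher and 1 lower of 15 (4 and 3 adjusted over the list alone), camera p 0.363, with Hoxa7 at 4.42 ± 0.41 (p 0.00016), their median being negative and camera's direction up.

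A last comparison asked whether genes of the dermis differ in KO epidermis. The 1268 genes at least 4-fold higher in dermis than in E9 epidermis were taken, a list that shares no library with KO or E13 Het epidermis but mixes tissue, age and library preparation. The 982 of them tested had a median log2 fold change of 0.25 in KO against Het epidermis, above all 10000 random lists matched on mean expression, whose median was 0.12. Of these genes 9 were called higher and 14 lower. Camera did not call the list (p 0.142, and p 0.671 with an estimated correlation), and random lists do not account for genes that move together. The standing above random lists was lost without E13 Het replicate 3 (median 0.33 against 0.27, above 94.1% of random lists) and without KO replicate 2 (0.05 against 0, above 92.2%). For the 200 largest folds, 66 of them tested, the median of 0.32 lay below that of the random lists, 0.36. Camera's p was 0.0235 without E13 Het replicate 2 (median 0.34) and 0.0101 without KO replicate 3 (median 0.33).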

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

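With DESeq2 the number of genes called was 824 in KO against Het, 1997 in E13 against E9 and 2172 in KO against E9, and with limma voom 656, 1729 and 2575, against 287, 952 and 1001 with edgeR. Genes called in both of the first comparisons in opposite directions numbered 352 with DESeq2. Leaving out 1 library of the 2 compared groups gave 182 (without E13 KO replicate 1) to 348 (without E13 Het replicate 3) genes in KO against Het, 569 (without E9 Het replicate 2) to 812 (without E13 Het replicate 3) in E13 against E9, where leaving out KO replicate 3 of the shared fit gave 1152, 557 (without E9 Het replicate 2) to 815 (without E13 KO replicate 3) in KO against E9, and 2934 (without dermis replicate 3) to 5269 (without E13 Het replicate 1) in epidermis against dermis. In an alternative chosen after seeing the data, without the library of each compared group with fewest genes detected, 225, 730, 727 and 4560 genes were called.

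Lists called fell from 9, 16, 6 and 15 to 2, 1, 1 and 0 with an estimated inter-gene correlation. With fry, 5 lists passed in KO against Het and 3 in KO against E9. The list of Hox genes of groups 6 to 13 in KO against E9 was called, in the direction opposite to its main value, without the 2 libraries with fewest genes detected (adjusted p 0.0343) and with a replicate block (0.00725). Without those libraries the suprabasal list in KO against E9 (0.0343), the endoderm list in KO against Het (0.0394), Hox genes of groups 6 to 13 in E13 against E9 (0.00136) and of groups 1 to 5 in epidermis against dermis (0.0268) were called too, and the hair list in KO against Het (0.0519) and the muscle list in E13 against E9 (0.246) were not.

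Same-numbered KO and Het libraries deviated together at r = -0.056, 0.253 and -0.059, and differently numbered ones at -0.170 to 0.146. Replicate numbers thus did not pair these libraries for replicates 1 and 3. The value for replicate 2 was the highest, so a link between the KO and Het libraries of that number cannot be excluded. With the replicate block in a fit of the 2 groups, 186, 615, 2021 and 3464 genes were called in the 4 comparisons, where the first 3 gave 243, 914 and 1302 in such a fit without it, and 10 lists passed in KO against E9. E9 replicate 4 and E13 replicate 3 have no partner number, so in the E9 comparisons this fit rests on replicates 1 and 2 and on 1 residual degree of freedom.

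The median of dermis-enriched genes in the KO was 0.52 (camera p 5.9e-06) for a list taken against E13 Het epidermis, which shares the Het libraries, and 0.32 for the 200 largest folds, which lay above only 42.1% of random lists (median 0.357) and where camera's direction was down (p 0.654). It ran from 0.0474 (without E13 KO replicate 2) to 0.34 (without E13 Het replicate 2). Over all alternatives no named gene that was called in the main fit or in the alternative reversed. Named genes called in neither changed sign in 10, 5, 6 and 3 refits of the 4 comparisons. Calls of named genes were lost in 141 of 864, 120 of 1363, 146 of 1361 and 41 of 1803 refits of a called gene in the 4 comparisons.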

Other observations

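Krt8 and Krt18 were far higher in 1 of the 3 E13 Het libraries than in the others, though both below the KO means. The tests of this pattern were chosen only after it was seen. Krt8 stood at 74.7, 23.3 and 680 CPM in E13 Het replicates 1, 2 and 3 and Krt18 at 32.5, 27.9 and 447 CPM, against KO means of 918 and 827 CPM. If KO material had entered replicate 3, or its label were wrong, Trp63 and the p63-activated genes at least 4-fold higher in the other Het libraries than in KO would ask for 1 common share of KO material. These 14 genes gave a median share of 22.7% with an interquartile range of 25.03, and Krt8 and Krt18 gave 72.7% and 52.3%. A mixture is therefore not likely to account for both keratins, but these shares do not exclude a smaller one. Replicate 3 had no count of the Y-linked genes Ddx3y, Eif2s3y and Kdm5d. All 3 KO libraries held them, with Ddx3y at 51.0 to 64.6 CPM of the raw totals, which argues against material from those libraries. E9 material gave a median share of 0.345% over 7 early embryonic genes, where Krt8 and Krt18 would need 145% and 103%, which argues against it as well. A larger share of suprabasal or periderm cells remains open: 6 of the 10 tested suprabasal and periderm genes were highest in replicate 3, among them Evpl, Ppl and Tgm1, but Krt10, Krt4 and Krt17 were not. Separate libraries of sorted periderm cells could settle it.

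The dermal mesenchyme list was higher in E13 than in E9 Het epidermis, but camera did not call it with an estimated correlation (adjusted p 0.250). The tests of this pattern were chosen only after it was seen. Of 23 members, Postn, Col5a1, Dcn, Col5a2 and Fbn1 passed. If dermal cells carried through the GFP sort were the source, these genes would ask for no larger a dermal share than the most abundant dermal transcripts Col1a1, Col1a2 and Col3a1 give. In the 3 E13 Het libraries they needed a median of 8.45%, 15.4% and 13.6% dermal RNA, where those collagen genes gave at most 0.795%, 4.74% and 0.791%, a ratio of at least 3.24. Carried-over dermal RNA is therefore not the likely source of the rise of these 5 genes as a whole. The ratio rests on medians, and Dcn lay nearest to the collagen genes, needing 1.72%, 7.8% and 3.98%. Pdgfra was not used in this test. It stood at 28.6, 58.1 and 11.45 CPM of the raw totals in these libraries, at 50.3, 21.2 and 27.2 at E9 and at 443 to 887 in dermis. For any rise of the members that did not pass, carried-over dermal RNA may be the source. Of these members, 83.3% were highest in replicate 2, the library with the most Col1a1. The called members other than Postn were highest there too, so this pattern does not set the called members apart from the rest. The dermal libraries were made by another preparation, so these shares are rough.

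The KO changes ran opposite to the changes from E9 to E13, and the tests of this pattern were chosen only after it was seen. Simulated unchanged groups that share the E13 Het libraries called at most 1 gene in opposite directions, where 137 were observed. Groups without real changes offer almost no gene to be called in both comparisons. This count therefore cannot test what the shared libraries add to real calls. The correlation was stronger in the simulated groups, at r = -0.498, than the observed r = -0.368. The covariance of the fold changes differed by -0.152 from the simulated mean of -0.520 ± 0.0226 (SD). It was itself -2.122 without E13 Het replicate 2, for which the simulation was not repeated. How far the difference depends on single libraries is therefore not known. The simulated groups hold no real effects, and 3 libraries cannot be split between the comparisons. The part that the shared libraries add therefore cannot be told apart from a shared biological course. Cells held at the E9 state would keep early embryonic genes at the E9 level. Basal genes would stay unchanged against E9 as well, unless the loss of Trp63 itself lowered them. The early embryonic list had a median of -1.76 in KO against E9, and 45% of the tested basal genes, 9 of 20, were called in that comparison, 3 higher and 6 lower. The early embryonic median argues against a simple arrest at E9. The basal calls cannot decide it, since Trp63 itself was lower in KO (24.6 CPM) than at E9 (223 CPM). A mixed state, with some genes past E9 and others below it, could give these values.

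Each comparison has 10 ways to split its 6 libraries into 3 and 3, and these tests were chosen only after the counts of called genes were seen. In each comparison only 1 split, the real one, called that many genes: 287, 952, 1001 and 4504, where the highest other split called 1, 0, 0 and 0. With 10 splits the smallest possible share is 10%, too few for a share under 0.05.

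Transcripts from the sex chromosomes varied between libraries of a group. E13 Het replicate 3 had 2191 CPM of Xist and no count of the Y-linked genes Ddx3y and Kdm5d, and dermis replicates 2 and 3 had 801 and 1308 CPM of Xist. Dermis replicate 1 had 2.98 CPM of Xist and 89.2 CPM of Ddx3y, and E9 replicate 1 and KO replicate 1 had 1.08 and 7.20 CPM of Xist. Most other epidermal libraries held both Xist and Y-linked transcripts, as pools of embryos of both sexes would. In E9 replicate 4, muscle genes were high, and the posterior gene Hoxc10 stood at 1.98 CPM against 99.9 and 53.8 CPM in replicates 1 and 2.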
